A study of Triticum aestivum with 6 samples.

How the data were processed

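RNA sequencing libraries of grain from a white-grained and a purple-grained wheat, 3 per grain type and collected 30 days after flowering, were analysed from a table of 107891 genes. Per the labels' protocols, plants grew in pots in a climate chamber, RNA was extracted with Trizol and libraries followed Illumina protocols. The submitters' processing notes name cutadapt, HISAT2 and StringTie. Their versions and roles, the strand setting, the genome build and the annotation were not given in the sources used here. Per the file headers, the deposited table holds a count for each gene and library, and its values are whole numbers. Per the file headers, the same table holds the authors' FPKM values, a measure scaled by the authors for gene length and library size; every value with a count of 0 (100%) was written as 0.0001 and was read here as 0. Gene identifiers, coordinates, descriptions and GO and KEGG terms were taken from the table, and no identifier matched the supplied reference gene table. The table holds 12 further measurement columns, from 6 libraries, that match none of the labelled samples and were not used here.

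Library totals were 78660932, 81075605 and 88002127 counts in white grain and 102868886, 98028719 and 80898310 in purple grain. The labels do not say whether libraries of a grain type came from separate plants, so p-values measure only the spread between these samples, which may be technical. No pair of libraries agreed within counting noise, and each was kept as a replicate. Errors are SD over 3 libraries unless SE is stated.

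The design set before the data were examined named limma on log2(FPKM + 1), to be replaced by edgeR if raw counts were present. Counts were present, so edgeR 4.0.16 in R 4.3.3 gave the main result, with TMM scaling, a trended dispersion, the quasi-likelihood test and no replicate block. Genes with a mean of at least 0.5 FPKM over the 6 libraries were tested, 48492 in all. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 difference of at least 1. The common biological coefficient of variation was 0.488. The SE of a log2 difference was its size divided by the square root of the F statistic. Where a group had 0 counts, the fold is a lower bound computed with 3 counts per library in that group. Such bounds cover counting error only.

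Gene lists, 32 in number and set before the data were examined, were defined by patterns on the descriptions. They were tested with camera (limma 3.58.1) on log2(FPKM + 1) with an inter-gene correlation of 0.01, adjusted over lists and unions of lists with at least 3 tested members. Of the 32 lists, 8 passed, and none of these calls held with an estimated correlation (adjusted p = 0.951). The adjustment gave these 8 the same value. Their unadjusted camera p with an estimated correlation ran from 0.0604 for embryo and aleurone and 0.0971 for LEA and dehydrin to 0.531 for storage proteins. Terms with 10 to 500 tested genes were tested against all tested genes with a one-sided Fisher's exact test. Chromosomes were compared with two-sided Fisher's exact tests. Each was adjusted over terms or chromosomes and both directions. Descriptions name a matching protein, often of a related species, and do not establish an enzyme's activity. Copies of a gene on the A, B and D subgenomes can share reads, so values of single copies are uncertain.

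The rule for the genes named was set before the data were examined. It took the 6 largest rises and 6 largest falls among called genes with no overlap between groups, a mean of at least 5 FPKM in the higher group and an informative description. For each phenylpropanoid and flavonoid list it took the member with the highest mean and the called member with the smallest adjusted p. For each other list it took the 2 called members with the largest change at a mean of at least 1 FPKM. Where none was called, it took the member with the highest mean. Some genes chosen for these other lists were left out of the text, also where another gene of the list is named. Genes outside the rule are marked as chosen after their values were seen.

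Alternatives covered the pseudocount, the filter, the scaling, the variance model, a replicate block, the thresholds and leaving out each library. DESeq2 1.42.0, limma on log2(FPKM + 1), lists and terms without the lowered part of chromosome 1B, and flavonoid lists by KO number were added after seeing the data. The ranges of called members of a list cover 11 alternatives, those of scaling, filter, variance model and test including limma and DESeq2, without the replicate block and the left-out libraries. The steps were tested on simulated counts for the 48492 tested genes. Of 50 genes changed at each size, edgeR recovered 0% at 2-fold, 12% at 4-fold, 40% at 8-fold and 62% at 16-fold, and it called 3 unchanged genes. Far fewer genes were changed there than the 12967 with an unadjusted edgeR p under 0.05 in the data. The adjusted threshold was therefore stricter, and these shares are not the power of the real comparison. A simulated list raised 4-fold passed camera, as did 0 of 200 unchanged lists. Simulated genes were drawn independently, so this cannot show how often unchanged lists of correlated genes pass. Estimated correlations were 0.486 for the LEA and dehydrin list and 0.673 for the photosynthesis list. A planted term and a planted chromosome passed Fisher's test, with 0 other terms enriched and 0 other chromosomes raised.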

Results

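Gene expression was measured by RNA sequencing in grain of a white-grained and a purple-grained bread wheat (Triticum aestivum) 30 days after flowering, with 3 libraries per grain type. Anthocyanins, the flavonoid pigments of purple wheat grain, are the subject of the study. The comparison asks which transcripts differ between grain of the white-grained and of the purple-grained wheat. Grain colour coincides here with every other genetic difference between these wheats. A called gene therefore cannot be assigned to pigment rather than to genetic background. The tissue label gives grain, whereas the extraction protocol in the labels speaks of stems and buds. Storage protein genes, which are expressed in the starchy endosperm, held 12.9% to 35.1% of summed FPKM in the 6 libraries. Library totals ran from 78660932 to 102868886 counts, with 65058 to 68885 genes counted per library.

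Purple grain had higher levels of wheat germ agglutinin and of a regulator gene of the Lc type. Single genes described as chalcone synthase, flavonol synthase and dihydroflavonol reductase were also higher. Purple grain had lower levels of most expressed genes in the first part of chromosome 1B. Single omega-gliadin genes, in that part or without a chromosome, were also lower. Of the 19 lower storage protein genes, 14 lay in that part. The most expressed chalcone synthase gene had 13.6 ± 6.01 FPKM in white and 0.260 ± 0.451 in purple grain (edgeR adjusted p = 0.118). With membership by KO number, chosen after seeing the data, edgeR called 0 of 8 tested dihydroflavonol reductase genes. In all, 1391 genes were higher and 1127 lower in purple grain among 48492 tested (edgeR adjusted p under 0.05 and a log2 difference of at least 1). Of these, 211 higher genes had 0 counts in all white libraries and 194 lower genes had 0 counts in all purple libraries. Whether such genes are absent or diverged in the plants of the grain type without counts was not tested on sequence. By the authors' FPKM, without TMM scaling, the purple libraries lay all above the white ones for 13.3% of tested genes and all below for 19.9%. For a single gene, chance gives 10% for both directions together. Genes are correlated, so these shares are not a test against that 10%. Without purple replicate 2 the test called 229 higher and 351 lower, without white replicate 2 it called 385 and 390, without white replicate 3 it called 402 and 405, without purple replicate 1 it called 684 and 562, and without purple replicate 3 it called 2562 and 2411. Of the called genes 55.2% were higher, against 46.7% with libraries scaled to total counts, which moved the median log2 difference of all tested genes from 0.02 to -0.11. Scaling to counts outside the 100 highest genes moved that median to -0.098.

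Purple replicate 3 stood apart from the other purple libraries. Across genes, which are not independent replicates, its log2 expression correlated at 0.885 and 0.8915 with purple replicates 1 and 2, which correlated at 0.945 with each other, and at 0.836 to 0.864 with the white libraries. Purple replicates 1 and 2 correlated at 0.723 to 0.822 with the white libraries, and the white libraries at 0.898 to 0.948 with one another. The first principal component took 59.8% of the variance and separated the grain types, with purple replicate 3 nearest to the white libraries. Storage protein genes held 35.1% of summed FPKM in purple replicate 3, against 12.9% and 13.4% in purple replicates 1 and 2 and 19.2% to 32.3% in white grain. The 100 genes with the highest mean held 33.5% ± 6.97 of summed FPKM in white and 31.4% ± 10.9 in purple grain (SD, n = 3; exact two-sided permutation p = 0.9, where the smallest possible is 0.1).

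**Figure D1:**
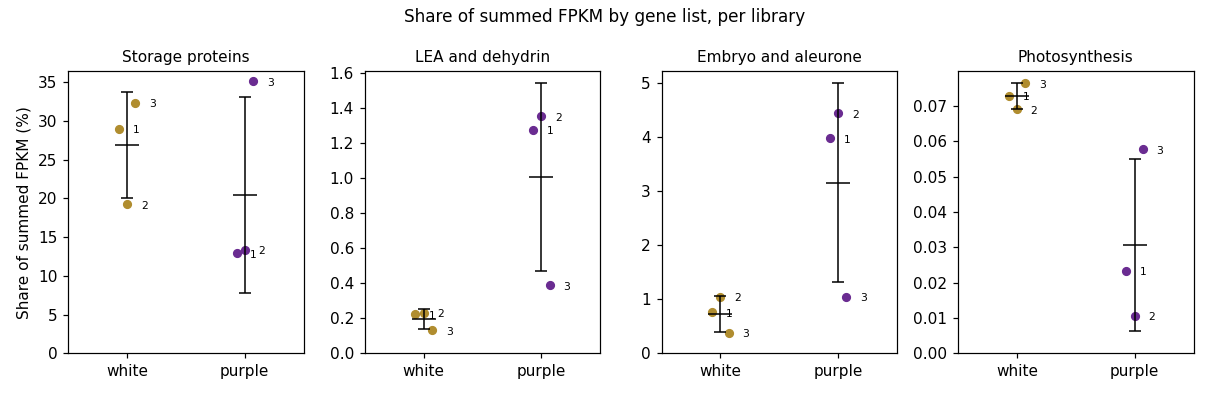
Share of summed FPKM (percent, y axis) held by 4 gene lists in white and purple grain, with points for libraries numbered by replicate and bars for the mean ± SD of 3 libraries. Purple replicate 3 lies at 35.1% for storage proteins and 0.387% for late embryogenesis abundant (LEA) and dehydrin genes, apart from purple replicates 1 and 2.

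Chalcone synthase, which makes the first flavonoid of the pathway, had 3 higher genes of 10 tested (1 to 5, with 0 to 2 lower, over 11 alternatives of scaling, filter, variance model and test). TraesCS2B02G048400 (chromosome 2B, 24089443 to 24091066) had 0 counts in white grain and 2.58 ± 0.991 FPKM in purple grain (SD, n = 3), at least 122-fold higher (edgeR adjusted p = 0.00854), and stayed called without any single library. TraesCS2A02G527700 and TraesCS2B02G558400, named after their values were seen, had 0 counts in white and 1.86 ± 1.12 and 1.30 ± 0.795 FPKM in purple grain (edgeR adjusted p = 0.0224 and 0.0264). Without white replicate 2, white replicate 3 or purple replicate 2, the test called 1 chalcone synthase gene higher. The member with the highest mean, TraesCS4D02G351300, had 13.6 ± 6.01 FPKM in white and 0.260 ± 0.451 in purple grain, which did not pass (edgeR adjusted p = 0.118; 0.00356 to 0.256 over 18 alternatives). Without purple replicate 3 it was called lower (edgeR adjusted p = 0.0101), and 2 members in all were. The counts adjusted over the list alone were 5 higher and 3 lower. At a mean of at least 1 FPKM, 1 of 4 tested members was higher. Camera did not pass the list (adjusted p = 0.220), but passed it with membership by KO number, chosen after seeing the data (adjusted p = 0.0109, 3 higher of 6 tested), where the list by description had an adjusted p of 0.951 with an estimated correlation.

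Cinnamate 4-hydroxylase, an enzyme of the general phenylpropanoid route upstream of chalcone synthase, had 1 higher gene of 4 tested (1 to 2 over 11 alternatives), and 1 adjusted over the list alone. TraesCS2D02G300200 (2D, 382380184 to 382385377) stood at 2.35 ± 1.85 FPKM in white and 38.8 ± 18.2 in purple grain, a log2 difference of 4.22 ± 0.64 (SE; edgeR adjusted p = 0.0196). The call was lost without white replicate 3, purple replicate 1 or purple replicate 2, with an adjusted p up to 0.0732. The most expressed member, TraesCS3D02G136900, had 20.8 ± 6.91 and 27.8 ± 22.1 FPKM (edgeR adjusted p = 0.560). Phenylalanine ammonia-lyase, the entry enzyme, had 0 called genes of 17 by edgeR, with 1 lower at an unadjusted p under 0.05 and 1 lower by DESeq2. The median log2 difference of the 17 was 0.94, with 13 above 0, and camera did not pass the list (adjusted p = 0.351). The most expressed phenylalanine ammonia-lyase gene, TraesCS6D02G212400, had 28.8 ± 7.96 and 29.2 ± 16.1 FPKM (edgeR adjusted p = 0.897). The most expressed 4-coumarate-CoA ligase gene, TraesCS6A02G151700, had 13.8 ± 4.77 and 14.5 ± 11.7 FPKM (edgeR adjusted p = 0.881).

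Genes described as flavonol synthase/flavanone 3-hydroxylase, oxygenases of the middle of the flavonoid pathway, had 3 higher of 16 tested in the flavanone 3-hydroxylase list, and the same 3 were the higher ones of 15 tested in the flavonol or flavone synthase list, which shares 10 tested genes with it (2 to 6 higher in either, and 0 to 1 lower in the second, over 11 alternatives). TraesCS1D02G319700 (1D, 413729433 to 413731794) had 0 counts in white and 5.00 ± 1.86 FPKM in purple grain, at least 172-fold higher (edgeR adjusted p = 0.00761), and stayed called without any single library. TraesCS1B02G332200 had 0 counts in white and 2.57 ± 1.5 FPKM in purple grain, and TraesCS1A02G320000 had 0.010 ± 0.0173 and 2.48 ± 2.59 FPKM (edgeR adjusted p = 0.0196 and 0.0393; both named after their values were seen). The call of TraesCS1A02G320000 was also lost without white replicate 3 (2 higher members). In either list, 1 member was higher without white replicate 2, purple replicate 1 or purple replicate 2. The most expressed members, TraesCS7B02G042500 and the flavone O-methyltransferase gene TraesCS7B02G245500, had 6.79 ± 6.65 and 25.4 ± 19.9 FPKM, and 37.2 ± 13.7 and 37.8 ± 33.1 FPKM (edgeR adjusted p = 0.30 and 0.925). For the first list 3 genes were higher adjusted over the list alone, and for the second 4 were higher and 1 lower. The second list had 1 lower gene without purple replicate 3. Both lists passed camera (adjusted p = 0.0309 each), but not with an estimated correlation (adjusted p = 0.951 each). Neither list passed without white replicate 2 (adjusted p = 0.127 and 0.123), white replicate 3 (0.0558 each) or purple replicate 1 (0.171 each). With membership by KO number, chosen after seeing the data, the first list had 0 calls by edgeR of 6 tested, 0 at an unadjusted p under 0.05 and 0 by DESeq2, and did not pass (adjusted p = 0.879; 0.00571 to 0.951 over 18 alternatives with camera, and 0.00413 to 0.951 for the second list). By KO number the second list had 5 higher and 1 lower of 64 tested, 11 of them in the list by description, and passed camera (adjusted p = 0.0459).

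Dihydroflavonol 4-reductase, which forms the leucoanthocyanidins, had 3 higher genes and 1 lower of 42 tested (2 to 7 and 0 to 6 over 11 alternatives). TraesCS4A02G331600 (4A, 616230264 to 616234476) stood at 5.35 ± 1.83 FPKM in white and 35.3 ± 11.8 in purple grain, a log2 difference of 2.82 ± 0.39 (SE, edgeR adjusted p = 0.0160). The other called genes were named after their values were seen. TraesCS7A02G396100 had 4.22 ± 2.54 and 22.4 ± 3.43 FPKM, and TraesCS5D02G541100 had 19.4 ± 3.47 and 38.7 ± 6.86 FPKM (edgeR adjusted p = 0.0181 and 0.0468); the second call was kept only without purple replicate 3. TraesCS6D02G365700 had 1.40 ± 0.962 FPKM in white grain and 0 counts in purple grain, at least 61.6-fold lower (edgeR adjusted p = 0.0286). The member with the highest mean, TraesCS7B02G298900, had 27.8 ± 22.3 and 56.9 ± 22.8 FPKM (edgeR adjusted p = 0.25). Without white replicate 3 or purple replicate 2, edgeR called 0 members, where all libraries gave 8 higher and 6 lower at an unadjusted p under 0.05 and DESeq2 called 7 and 6. Without white replicate 2 it called 1 higher and 0 lower, without purple replicate 1 it called 2 and 0, and without purple replicate 3 it called 4 and 2. The counts adjusted over the list alone were 3 higher and 2 lower. Camera did not pass the list (adjusted p = 0.313). With membership by KO number, chosen after seeing the data, 8 genes were tested, 4 of them in the list by description. Of these 8 edgeR called 0, with 1 higher and 1 lower at an unadjusted p under 0.05 and 1 and 1 by DESeq2, and their median log2 difference was -0.23.

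Anthocyanidin synthase, which forms the coloured anthocyanidins, had 5 genes by description, none above the expression filter, so counts are given. TraesCS6D02G004300 (6D, 2106676 to 2108293) had 8, 12 and 0 counts in the white libraries and 104, 153 and 121 in the purple ones (edgeR adjusted p = 0.0831 without a filter). TraesCS6A02G001500 had 38, 7 and 0 counts against 142, 85 and 149 (edgeR adjusted p = 0.253 without a filter). TraesCS6A02G041800 had 43, 41 and 20 counts against 108, 31 and 72 (edgeR adjusted p = 0.453 without a filter). TraesCS6B02G006200 had 0 counts in white grain and 6, 2 and 0 counts in the purple libraries (edgeR adjusted p = 0.372 without a filter). TraesCS2B02G613000 had 0 counts in every library, and none of the other 4 passed the test. Membership by KO number, chosen after seeing the data, gave 14 genes, of which 5 were tested and 0 of these were in the list by description. Their median log2 difference was -0.93, and edgeR called 0, with 2 lower at an unadjusted p under 0.05 and 0 called by DESeq2.

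Leucoanthocyanidin reductase, which leads to proanthocyanidins, had 1 lower gene of 5 (0 to 1, with 0 to 1 higher, over 11 alternatives), and 1 adjusted over the list alone. TraesCS2D02G482100 (2D, 584661170 to 584663446) fell by 2.98 on the log2 scale, from 1.57 ± 0.171 to 0.181 ± 0.0733 FPKM (SE 0.46; edgeR adjusted p = 0.0213). The call was lost without white replicate 2, white replicate 3, purple replicate 1 or purple replicate 2, with an adjusted p up to 0.0716. The most expressed member, TraesCS2A02G481200, had 4.10 ± 3.47 and 1.51 ± 0.477 FPKM (edgeR adjusted p = 0.218). By KO number, chosen after seeing the data, edgeR called 0 of 13 tested leucoanthocyanidin reductase genes, 0 of them in the list by description, with 3 higher and 2 lower at an unadjusted p under 0.05 and 2 and 2 by DESeq2. Anthocyanidin reductase gene TraesCS2B02G507500, the most expressed of 6, had 27.1 ± 8.71 and 24.8 ± 17.2 FPKM (edgeR adjusted p = 0.998).

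Phenylalanine ammonia-lyase, 4-coumarate-CoA ligase, chalcone isomerase, flavonoid 3'-hydroxylase, flavonoid 3',5'-hydroxylase, anthocyanidin transferases, anthocyanidin reductase, WD40 regulators, MATE transporters and secondary wall genes had no call in the lists by description. The WD40 list had only 2 tested genes, both with a negative log2 difference and 1 at an unadjusted edgeR p under 0.05. The more expressed, TraesCS6A02G193300, is described as LWD1 and had 8.75 ± 2.49 FPKM in white and 4.42 ± 1.35 in purple grain (edgeR adjusted p = 0.134). With membership by KO number, chosen after seeing the data, 2 of 30 tested 4-coumarate-CoA ligase genes and 1 of 22 anthocyanidin reductase genes were lower. Over the 10 lists by description edgeR called 0 of 92 tested genes, 17 had an unadjusted p under 0.05, and DESeq2 called 10. Without purple replicate 3, edgeR called 8. Chalcone isomerase gene TraesCS5B02G488900 had 5.49 ± 2.21 FPKM in white and 2.02 ± 1.53 in purple grain (edgeR adjusted p = 0.215; 0.0409 to 0.476 over 18 alternatives), and was called lower without purple replicate 3 (edgeR adjusted p = 0.0409). Flavonoid 3'-hydroxylase gene TraesCS5D02G217400 had 3.30 ± 3.16 and 2.15 ± 1.11 FPKM, and flavonoid 3',5'-hydroxylase gene TraesCS4D02G224700 had 1.16 ± 1.27 and 2.06 ± 1.21 FPKM (edgeR adjusted p = 0.689 and 0.522). Anthocyanidin glucosyltransferase gene TraesCS2A02G009500 had 3.97 ± 2.73 and 5.56 ± 3.24 FPKM (edgeR adjusted p = 0.565). By counts adjusted over the list alone, 2 flavonoid 3',5'-hydroxylase genes and 3 anthocyanidin transferase genes were higher. Camera passed none of these lists with at least 3 tested members (adjusted p = 0.145 to 0.83), nor those of cinnamate 4-hydroxylase (0.151, and 0.951 with an estimated correlation) and leucoanthocyanidin reductase (0.220). By KO number cinnamate 4-hydroxylase passed camera (adjusted p = 0.0109), with 1 higher of 12 tested.

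**Figure D2:**
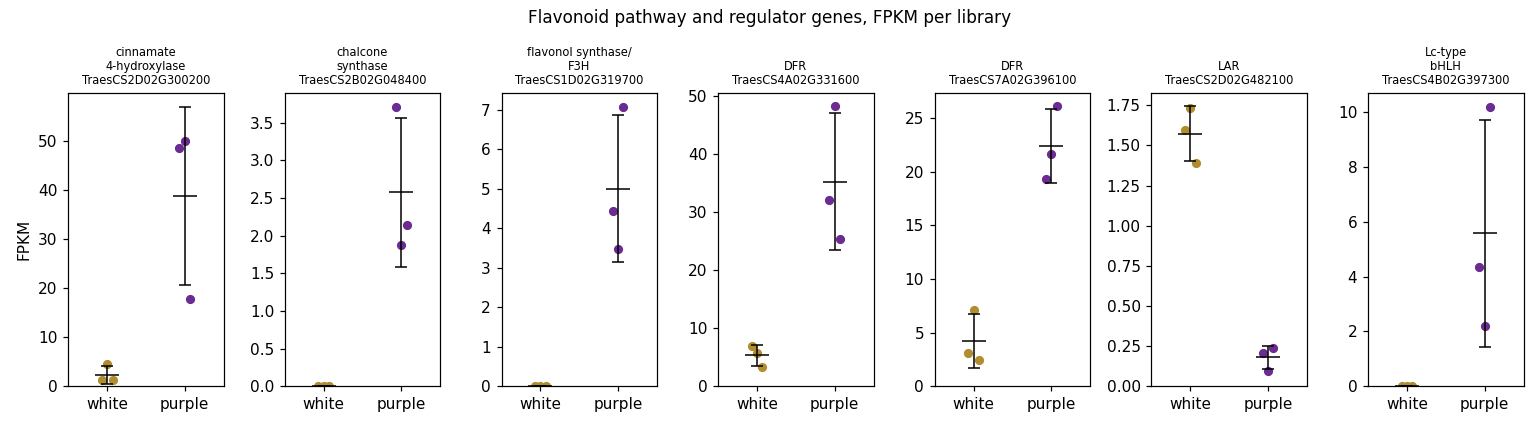
FPKM (y axis, own scale per gene) of flavonoid pathway and regulator genes in white and purple grain, with points for libraries and bars for the mean ± SD of 3 libraries; F3H, DFR and LAR stand for flavanone 3-hydroxylase, dihydroflavonol 4-reductase and leucoanthocyanidin reductase. Chalcone synthase TraesCS2B02G048400 and the Lc-type gene TraesCS4B02G397300 had 0 counts in every white library. Only called genes are shown, and TraesCS7A02G396100 was chosen after its values were seen. Not shown are the lower dihydroflavonol 4-reductase gene TraesCS6D02G365700 and the most expressed members that were not called. Among these is chalcone synthase TraesCS4D02G351300, with 13.6 FPKM in white and 0.260 in purple grain.

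Of 68 tested bHLH transcription factor genes, 6 were higher and 1 lower (2 to 16 and 0 to 3 over 11 alternatives). TraesCS4B02G397300 (4B, 671696059 to 671698835) is described as anthocyanin regulatory Lc protein, after the maize gene that activates anthocyanin synthesis. It had 0 counts in white grain and 4.33, 2.20 and 10.2 FPKM in the purple libraries, at least 216-fold higher (edgeR adjusted p = 0.0180), and the call was lost without white replicate 2 or purple replicate 1, with an adjusted p up to 0.0536. TraesCS4B02G193300, described as bHLH140, had 1.32 ± 0.219 FPKM in white and 3.05 ± 0.633 in purple grain (edgeR adjusted p = 0.0378). Its call was kept only without purple replicate 3. TraesCS6A02G335500 and TraesCS6D02G315200, both described as bHLH96 and named after their values were seen, had 0 counts in white and 1.72 ± 1.01 and 1.62 ± 0.891 FPKM in purple grain (edgeR adjusted p = 0.0186 and 0.0170). Both calls were lost without purple replicate 1 or purple replicate 2, and the first also without white replicate 2. Outside the lists and also chosen after its values were seen, TraesCS2A02G409400 (2A, 667010726 to 667015774), described as a MYC-like regulatory protein, had 0 counts in white grain and 164, 79 and 613 counts in the purple libraries (edgeR adjusted p = 0.0448). It stayed called only without purple replicate 3, with an adjusted p up to 0.102 without another library. The number of higher bHLH genes was 2 without white replicate 2, 3 without white replicate 3 and 1 without purple replicate 2. Without purple replicate 1 edgeR called 0 higher, where all libraries gave 17 at an unadjusted p under 0.05 and 12 by DESeq2. With no filter 16 were higher, with libraries scaled to total counts 3 were, and at a mean of at least 1 FPKM 2 were. The lower ones numbered 5 without purple replicate 3. Adjusted over the list alone, 7 were higher and 1 lower.

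Of 165 tested MYB genes, 3 were higher and 7 lower (2 to 10 and 5 to 17 over 11 alternatives), and 5 and 9 adjusted over the list alone. Myb-like protein J gene TraesCS7B02G093600 had 0 counts in white and 4.59 ± 3.79 FPKM in purple grain (edgeR adjusted p = 0.0268), a call lost without white replicate 2, white replicate 3, purple replicate 1 or purple replicate 2. R2R3-MYB gene TraesCS1B02G055200 (1B, 37798961 to 37800280), in the part of chromosome 1B where most expressed genes were lower, had 3.42 ± 2.17 FPKM in white grain and 0 counts in purple grain, at least 112-fold lower (edgeR adjusted p = 0.0127). Below the filter and chosen after its values were seen, myb-related gene TraesCS7D02G166500 had 8, 0 and 17 counts in white and 144, 32 and 38 in purple grain (edgeR adjusted p = 0.258 without a filter). The number of lower MYB genes was 1 without white replicate 2, 2 without white replicate 3, purple replicate 1 or purple replicate 2, and 13 without purple replicate 3. The number of higher MYB genes was 1 without white replicate 2 or white replicate 3 and 7 without purple replicate 3. Without purple replicate 2 edgeR called 0 higher, where all libraries gave 18 at an unadjusted p under 0.05 and 10 by DESeq2. Camera passed neither family (adjusted p = 0.372 for MYB and 0.220 for bHLH).

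Of 60 glutathione S-transferase genes, a family with members that help to move flavonoids into the vacuole, 2 were higher and 1 lower (2 to 14 and 0 to 1 over 11 alternatives), and 7 and 1 adjusted over the list alone. TraesCS5A02G502300 had 0 counts in white and 2.16 ± 0.203 FPKM in purple grain (edgeR adjusted p = 0.00876; lost without purple replicate 2). TraesCS4B02G059300 had 0.772 ± 0.623 and 14.7 ± 9.23 FPKM (edgeR adjusted p = 0.0348), a call kept only without purple replicate 3. The list passed camera (adjusted p = 0.0160), but not with an estimated correlation (adjusted p = 0.951) or without purple replicate 1 (adjusted p = 0.112; 0.000576 to 0.951 over 18 alternatives with camera). Higher members numbered 10 without purple replicate 3, 4 without purple replicate 1 and 1 without white replicate 2 or white replicate 3. Without purple replicate 2 edgeR called 0, where all libraries gave 19 higher and 4 lower at an unadjusted p under 0.05 and 14 and 1 by DESeq2. It called 0 lower without any other single library except white replicate 1. The lignin branch had 3 higher and 1 lower of 32 (2 to 7 and 1 to 6 over 11 alternatives), and 3 and 3 adjusted over the list alone. Its caffeic acid O-methyltransferase gene TraesCS2B02G066100 stood at 1.14 ± 0.620 and 25.02 ± 7.26 FPKM, a log2 difference of 4.57 ± 0.54 (SE, edgeR adjusted p = 0.0103), and 1 lignin gene was higher without white replicate 2 or white replicate 3. For the lower lignin genes edgeR called 0 without any single white library or without purple replicate 1, where all libraries gave 6 at an unadjusted p under 0.05 and 6 by DESeq2. Camera did not pass the lignin branch (adjusted p = 0.484).

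**Figure D3:**
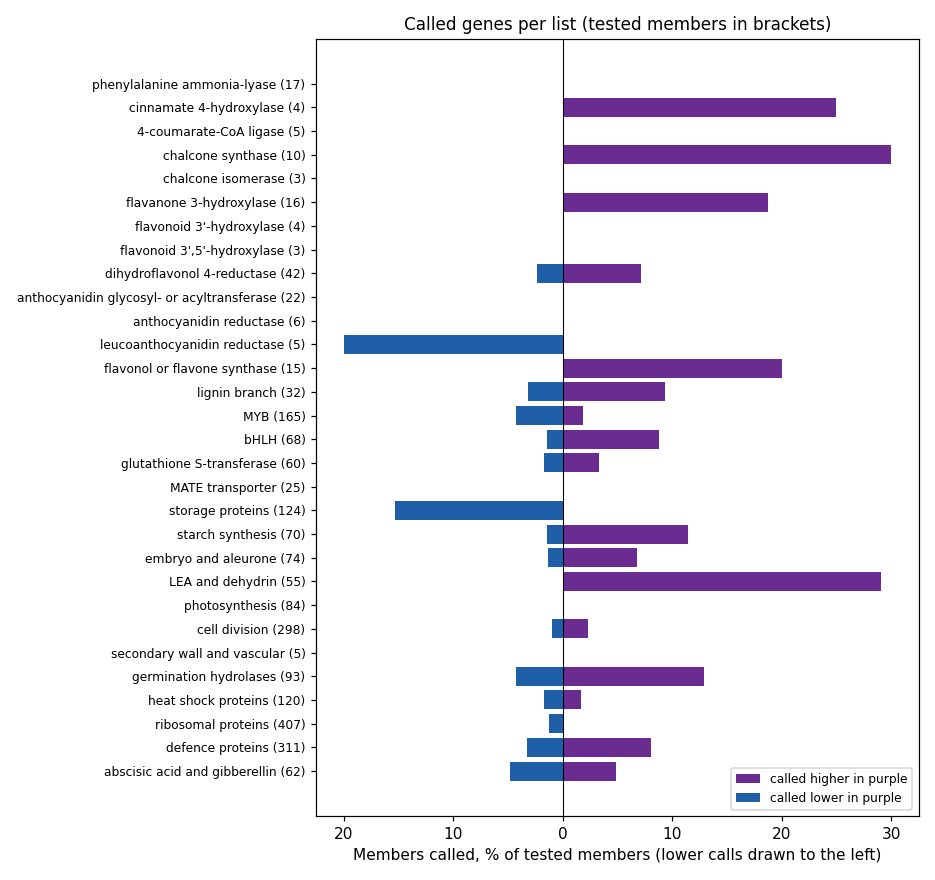
Called genes per list as a percentage of tested members (x axis; higher calls to the right, lower calls to the left), with tested members in brackets. The LEA and dehydrin list has 16 higher of 55 and the storage protein list 19 lower of 124.

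LEA proteins and dehydrins, which accumulate as seeds dry, had 16 higher genes of 55 tested (11 to 40 over 11 alternatives) and a median log2 difference of 2.39, with 52 members above 0. The list passed camera (adjusted p = 4.46e-18), but not with an estimated correlation (adjusted p = 0.951). Adjusted over the list alone, 40 were higher. Dehydrin DHN3 gene TraesCS6A02G350600 had 0.0407 ± 0.0361 FPKM in white and 14.3 ± 12.02 in purple grain (edgeR adjusted p = 0.0242), with 2.03 FPKM in purple replicate 3 against 14.8 and 26.0 in purple replicates 1 and 2. DHN3 gene TraesCS6A02G350900 had 0 counts in white and 4.80 ± 2.90 FPKM in purple grain (edgeR adjusted p = 0.0220). Both calls were lost without white replicate 2, white replicate 3, purple replicate 1 or purple replicate 2, where the list had 1, 3, 2 and 1 higher members. Without purple replicate 3 it had 31. The summed share of these genes was 1.27% and 1.35% in purple replicates 1 and 2, 0.387% in purple replicate 3 and 0.133% to 0.232% in white grain (exact two-sided permutation p = 0.1, the smallest possible).

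Embryo and aleurone genes had 5 higher and 1 lower of 74 (2 to 22 and 1 to 3 over 11 alternatives), and 14 and 2 adjusted over the list alone, while 2 were higher with no trend of the variance. The list passed camera (adjusted p = 0.000191), but not with an estimated correlation (adjusted p = 0.951). Em protein gene TraesCS1B02G237600 had 0 counts in white and 39.0 ± 44.3 FPKM in purple grain, a call kept only without purple replicate 3 (edgeR adjusted p = 0.0413). Lipid-transfer protein gene TraesCS2D02G476900 had 1.85 ± 1.29 and 36.1 ± 19.5 FPKM, a call lost without white replicate 3, purple replicate 1 or purple replicate 2 (edgeR adjusted p = 0.0378). The summed share was 3.98% and 4.44% in purple replicates 1 and 2, 1.05% in purple replicate 3 and 0.381% to 1.05% in white grain. Higher members numbered 13 without purple replicate 3, with 3 lower, 3 without white replicate 1 or white replicate 2, 2 without white replicate 3 and 1 without purple replicate 1. Without purple replicate 2 edgeR called 0, where all libraries gave 27 higher and 6 lower at an unadjusted p under 0.05 and 22 and 3 by DESeq2. It also called 0 lower without white replicate 2, white replicate 3 or purple replicate 1.

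Photosynthesis genes had a median log2 difference of -1.08, with 7 of 84 members above 0. The list passed camera (adjusted p = 1.42e-10), but not with an estimated correlation (adjusted p = 0.951). Single members were not called, with 0 of 84 by edgeR, also adjusted over the list alone, 10 at an unadjusted p under 0.05 and 4 by DESeq2 (0 to 4 lower over 11 alternatives). Without purple replicate 3, edgeR called 51 lower. The summed share was 0.0577% in purple replicate 3, 0.0234% and 0.0106% in purple replicates 1 and 2 and 0.0690% to 0.0763% in white grain.

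Starch synthesis had 8 higher and 1 lower of 70 (5 to 18 and 0 to 4 over 11 alternatives), and 14 and 3 adjusted over the list alone. Isoamylase removes branches from starch, and isoamylase 3 genes TraesCS5B02G246400 and TraesCS5D02G255800 had 0.187 ± 0.0525 and 3.59 ± 1.00 FPKM, and 0.372 ± 0.160 and 5.49 ± 1.49 FPKM (edgeR adjusted p = 0.00638 and 0.00905). Both stayed called without any single library. The median and mean differences of the list were -0.11 and -0.35, while camera gave an upward direction and did not pass (adjusted p = 0.880). Higher members numbered 3 without white replicate 2 or purple replicate 2, 4 without white replicate 1 or white replicate 3 and 5 without purple replicate 1. The counts were 11 higher and 24 lower without purple replicate 3. Without any other single library edgeR called 0 lower, where all libraries gave 4 at an unadjusted p under 0.05 and 4 by DESeq2.

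Germination hydrolases had 12 higher and 4 lower of 93 (9 to 22 and 2 to 9 over 11 alternatives), and 20 and 7 adjusted over the list alone. The list passed camera (adjusted p = 0.0309), but not with an estimated correlation (adjusted p = 0.951). Nor did it pass without white replicate 2, white replicate 3 or purple replicate 1 (adjusted p = 0.0692, 0.149 and 0.0746; 0.0168 to 0.951 over 18 alternatives with camera). Serine carboxypeptidase-like gene TraesCS1A02G331100 had 0 counts in white and 2.82 ± 0.336 FPKM in purple grain (edgeR adjusted p = 0.00576), and stayed called without any single library. Higher hydrolase genes numbered 1 without purple replicate 2, 3 without white replicate 2, 4 without white replicate 3 and 5 without purple replicate 1. Lower hydrolase genes numbered 1 without white replicate 1 or white replicate 3, 2 without white replicate 2 and 8 without purple replicate 3. Without purple replicate 1 or purple replicate 2 edgeR called 0 lower, where all libraries gave 10 at an unadjusted p under 0.05 and 9 by DESeq2. Defence proteins had 25 higher and 10 lower of 311 (23 to 58 and 9 to 42 over 11 alternatives), and 46 and 28 adjusted over the list alone, and camera did not pass them (adjusted p = 0.315). Higher defence genes numbered 5 without purple replicate 2, 10 without white replicate 2, 12 without white replicate 3, 16 without purple replicate 1 and 44 without purple replicate 3. Lower ones numbered 2, 4, 4, 5 and 22 in the same order.

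Abscisic acid and gibberellin genes had 3 higher and 3 lower of 62 (1 to 14 and 0 to 8 over 11 alternatives), and 10 and 5 adjusted over the list alone. Tested with no trend of the variance 1 was higher, and at a mean of at least 1 FPKM edgeR called 0 lower, where the main test gave 3. TraesCS4D02G076400, described as a gibberellin stimulated transcript, had 0.164 ± 0.284 and 52.9 ± 17.3 FPKM (edgeR adjusted p = 0.0341), a call lost without white replicate 2, white replicate 3, purple replicate 1 or purple replicate 2. Without purple replicate 3, 10 members were higher and 8 lower, and without white replicate 2, white replicate 3, purple replicate 1 or purple replicate 2, 1 was lower. Without white replicate 2, purple replicate 1 or purple replicate 2 edgeR called 0 higher, where all libraries gave 17 at an unadjusted p under 0.05 and 14 by DESeq2. Cell division genes had 7 higher and 3 lower of 298 (6 to 24 and 3 to 13 over 11 alternatives), with 13 higher without purple replicate 3, 4 without purple replicate 1, 3 without purple replicate 2 and 1 without white replicate 3. Without white replicate 2 edgeR called 0 cell division genes higher, where all libraries gave 30 at an unadjusted p under 0.05 and 24 by DESeq2. Lower cell division genes numbered 6 without white replicate 1, 5 without purple replicate 3 and 1 without white replicate 2, purple replicate 1 or purple replicate 2. Without white replicate 3 edgeR called 0 lower, where all libraries gave 18 at an unadjusted p under 0.05 and 13 by DESeq2. Adjusted over the list alone, 6 cell division genes were higher and 3 lower. Heat shock proteins had 2 higher and 2 lower of 120 (2 to 13 and 1 to 11 over 11 alternatives), and 2 and 1 adjusted over the list alone, with 7 higher without purple replicate 3, 4 higher and 4 lower without white replicate 1, and 1 of each without any other single library. Ribosomal proteins had 5 lower of 407 (5 to 11, with 0 to 6 higher, over 11 alternatives), and 4 adjusted over the list alone, with 9 lower without purple replicate 3, 3 without purple replicate 1 or purple replicate 2 and 2 without white replicate 2 or white replicate 3. Leaving out white replicate 1 gave 2 higher and 6 lower ribosomal protein genes. The ribosomal list had a median of 0.04 and a mean of -0.08, and camera did not pass it (adjusted p = 0.835). Nor did camera pass abscisic acid and gibberellin, cell division or heat shock genes (adjusted p = 0.593, 0.329 and 0.372).

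Fitted rises were ranked among called genes with an informative description, no overlap between groups and a purple mean of at least 5 FPKM. The largest were those of wheat germ agglutinin, a chitin-binding lectin. Where white grain had 0 counts, the fitted size depends on the prior count. Agglutinin isolectin 2 gene TraesCS1D02G328900 (1D, 420378924 to 420379950) had 0 counts in white and 80.2 ± 43.8 FPKM in purple grain, at least 2621-fold higher (edgeR adjusted p = 0.00885). Agglutinin isolectin 3 gene TraesCS1B02G340200 (1B, 568005579 to 568006599) had 0 counts in white and 63.5 ± 31.0 FPKM in purple grain, at least 2060-fold higher (edgeR adjusted p = 0.00814). Histone H2B.3 gene TraesCS4B02G002800 at 46.05 ± 45.1 FPKM and lipoxygenase 3 gene TraesCS5D02G513100 at 8.39 ± 5.12 FPKM also had 0 counts in white grain (edgeR adjusted p = 0.0224 and 0.0114). So did cytochrome P450 genes TraesCS5B02G007100 and TraesCS5D02G014200, at 7.30 ± 4.38 and 6.61 ± 4.06 FPKM in purple grain (edgeR adjusted p = 0.0155 and 0.0127). The histone call was lost without white replicate 2 or white replicate 3, and that of TraesCS5B02G007100 without purple replicate 2.

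Storage proteins had 19 lower genes of 124 tested (17 to 24 over 11 alternatives), and 22 adjusted over the list alone. The count of higher genes was 0 by edgeR, with 3 at an unadjusted p under 0.05 and 2 by DESeq2. Fast omega-gliadin gene TraesCS1B02G011463 (1B, 5354835 to 5356085) had 182 ± 86.8 FPKM in white grain and 0 counts in purple grain, at least 6680-fold lower (edgeR adjusted p = 0.00463). Omega-gliadin genes TraesCSU02G210181, TraesCS1B02G011474 and TraesCSU02G165233 had 414 ± 196, 96.9 ± 36.8 and 93.8 ± 43.3 FPKM in white grain and 0 counts in purple grain (edgeR adjusted p = 0.00496, 0.00442 and 0.00550). Low molecular weight glutenin gene TraesCS1A02G010900 had 1515 ± 2040 and 0.0351 ± 0.0307 FPKM (edgeR adjusted p = 0.0265), a call lost without white replicate 2, purple replicate 1 or purple replicate 2. The list passed camera (adjusted p = 0.000886), but not with an estimated correlation (adjusted p = 0.951). Of the 19 lower genes 14 lay in the lowered part of chromosome 1B, and without that part, an alternative chosen after seeing the data, camera did not pass the list (adjusted p = 0.207; 1.38e-10 to 0.951 over 18 alternatives with camera). It did not pass without purple replicate 1 either (adjusted p = 0.112). Lower members numbered 9 without purple replicate 2, 11 without purple replicate 1 and 29 without purple replicate 3, the purple library with the highest storage protein share. Gliadin and glutenin genes have near-identical copies that can share reads, so their single values are uncertain.

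Chromosome 1B held 380 of the 1127 lower genes, 18.3% of its 2081 tested genes (two-sided Fisher's exact test, adjusted p = 1.37e-234). Most lay between the start of the chromosome and position 238675576, a boundary set from the data, where 350 of 513 tested genes were lower and 1 higher. On the rest of 1B, 30 of 1568 were lower and 60 higher. Ubiquitin ligase UHRF2 gene TraesCS1B02G007900 and chymotrypsin inhibitor gene TraesCS1B02G036100 had 19.2 ± 6.57 and 34.6 ± 17.8 FPKM in white grain and 0 counts in purple grain, at least 1358-fold and 577-fold lower (edgeR adjusted p = 0.00463 and 0.00942). The 40S ribosomal protein S7 gene TraesCS1B02G146100 had 62.3 ± 20.6 and 3.81 ± 0.817 FPKM, a log2 difference of -3.93 ± 0.36 (SE, edgeR adjusted p = 0.00601). This part held 14 of the 19 lower storage protein genes, 4 of the 10 lower defence genes, 3 of the 5 lower ribosomal protein genes, 2 of the 7 lower MYB genes and the 1 lower gene each of the bHLH and starch synthesis lists. Outside this part of 1B, 777 genes were lower. Without white replicate 2, white replicate 3 or purple replicate 2 the share of lower genes on 1B was 9.42%, 10.3% and 9.66%. Genes without a chromosome had 31 lower of 558 (adjusted p = 0.000126).

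**Figure D4:**
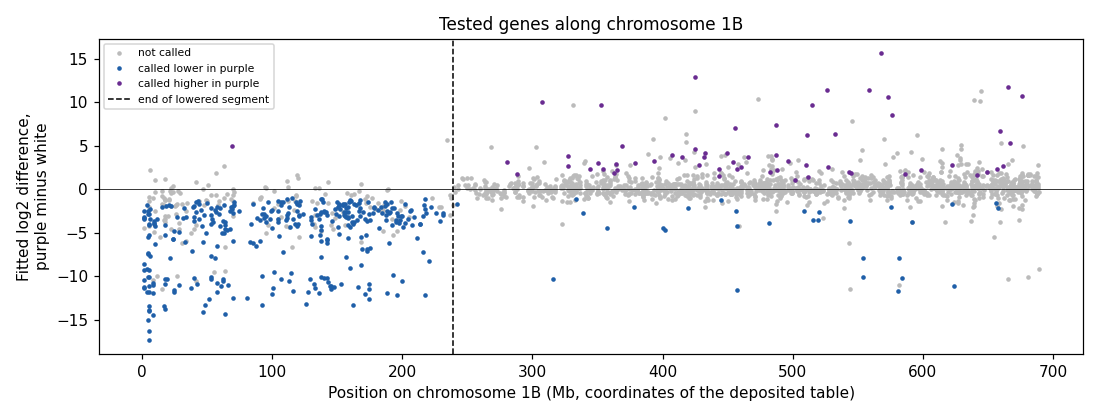
Fitted log2 difference, purple minus white grain (y axis), of each tested gene by its start on chromosome 1B (x axis, Mb), with colours for called genes and a dashed line at position 238675576. To the left of the line 350 of 513 genes were called lower and to its right 30 of 1568; the fitted difference of genes with 0 counts in a group depends on the prior count.

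Of 2313 GO and KEGG terms tested, 14 were enriched among higher genes and 2 among lower genes by one-sided Fisher's exact tests. Without the lowered part of chromosome 1B, an alternative chosen after seeing the data, the numbers were 16 and 6. Plant-type cell wall had 41 higher genes against 11.4 expected (adjusted p = 1.11e-08), cold acclimation 20 against 3.24 (adjusted p = 1.81e-07) and secondary metabolite biosynthesis 19 against 4.82 (adjusted p = 0.000245). Biosynthesis of benzoxazinoids, defence compounds of grasses, had 12 higher genes against 1.26 expected (adjusted p = 4.12e-06). They included the P450 genes TraesCS5B02G007100 and TraesCS5D02G014200 and, chosen after its values were seen, glucosyltransferase gene TraesCS7B02G016800 at 0.675 ± 0.197 and 10.2 ± 6.56 FPKM (edgeR adjusted p = 0.0258). The glucosyltransferase call was lost without white replicate 2, white replicate 3, purple replicate 1 or purple replicate 2, and that of TraesCS5B02G007100 without purple replicate 2. Enzyme inhibitor activity had 6 lower genes against 0.767 expected (adjusted p = 0.0310). Fisher's test counts copies of a gene on the A, B and D subgenomes as independent, so these p-values may be too small. Enriched terms numbered 7 without white replicate 2, 10 without white replicate 3, 26 without purple replicate 1, 0 without purple replicate 2 and 142 without purple replicate 3, and 159 with DESeq2 calls.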

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

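DESeq2, limma on log2(FPKM + 1), the analyses without the lowered part of chromosome 1B and membership by KO number were chosen after seeing the data. No called gene was called in the opposite direction under any alternative run. Against 1391 higher and 1127 lower genes, DESeq2 called 4561 and 3008, an adjusted p under 0.01 gave 167 and 251, limma on log2(FPKM + 0.1) gave 2008 lower, and leaving out a library gave 229 to 2562 higher and 351 to 2411 lower. The stricter threshold lowers counts by construction; the cause of the other moves was not tested. Of 8 gene list calls, 5 were left with median-of-ratios scaling, 5 with quantile normalization, 0 with an estimated correlation and 0 with fry, while 19 passed fry's mixed test of change in either direction and 3 to 12 passed when a library was left out. A robust variance was not run for lists, because camera has no such option. Enriched terms (term enrichment) numbered 16 in the main test, 68 with limma on log2(FPKM + 0.1), 25 with no filter, 159 with DESeq2 and 0 to 142 when a library was left out, and the cause was not tested. The share of 1B genes called lower was 9.42% to 19.7% when a library was left out, against 18.3%, with a Fisher p under 0.05 in each alternative run. The labels do not say whether replicate numbers pair the libraries, and not every pair passed a correlation of 0.1: deviations from group means correlated at 0.183, 0.00657 and 0.336 for numbers 1, 2 and 3. Libraries 1 and 3 of each grain type correlated best with their own number, while white replicate 2 correlated best with purple replicate 1 and purple replicate 2 with white replicate 1. The replicate block gave 1551 higher and 996 lower genes, with 890 of the 1391 and 731 of the 1127 still called. It gave 2 higher bHLH genes against 6, 5 MYB against 3, 5 glutathione S-transferase against 2, 11 embryo and aleurone against 5 and 8 abscisic acid and gibberellin genes against 3. Lower genes were 0 against 3 for abscisic acid and gibberellin, 5 against 2 for heat shock, 2 against 4 for germination hydrolases, 3 against 5 for ribosomal proteins, 2 against 1 for starch synthesis, 1 against 0 for photosynthesis, and 0 against 1 each for dihydroflavonol 4-reductase, lignin and glutathione S-transferase. In simulated data edgeR recovered 0% of 2-fold changes, of which part failed by the minimum log2 difference of 1 (median fitted size 0.96), and 12% of 4-fold changes. Far fewer genes were changed there than in the data, so these shares are not the power of the real comparison.

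For named genes, 1166 results kept direction and side of the threshold, 190 lost the call, 5 gained it and 35 changed sign. The sign changes were in genes called neither in the main test nor in that alternative, and their cause was not tested. The log2 difference of gene TraesCS6D02G212400 was -0.11 with limma on log2(FPKM + 0.1), -0.00067 with total counts, -0.039 with quantile normalization, -0.025 outside the 100 highest genes, -0.097 with limma on log2(FPKM + 1) and -0.31 to 0.47 when a library was left out. That of gene TraesCS6A02G151700 was -0.17, -0.033, -0.070 and -0.14 with limma on log2(FPKM + 0.1), quantile normalization, the replicate block and limma on log2(FPKM + 1), and -0.67 to 0.54 without a library. In that order, gene TraesCS7B02G245500 had -0.26, -0.16, -0.14 and -0.24, then -0.0055 outside the 100 highest genes and -0.82 to 0.51 without a library. In the same order, gene TraesCSU02G270000, a photosystem gene, had -1.08, -0.72, -0.63 and -0.79, and -0.80 to 0.73 without a library. For gene TraesCS2B02G507500 it was 0.019 at a mean of at least 1 FPKM, 0.0040 with median-of-ratios scaling, 0.0039 with DESeq2 and -0.41 to 0.49 without a library. Without a library, the range was -0.28 to 0.89 for gene TraesCS3D02G136900, -1.05 to 0.72 for gene TraesCS5D02G217400 and -0.67 to 0.22 for the MATE transporter gene TraesCS5D02G332300.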

Other observations

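The 20 Mb windows, the boundary on chromosome 1B and the tests of an absent or diverged segment, of mixed RNA, of a swap, of maturation and of embryo or aleurone share were chosen only after the results were seen. Of 685 windows 16 held more lower genes than the rest, 12 of them on 1B, and 3 held more higher genes. The first 20 Mb of chromosome 2A had 34 lower genes of 113 tested (Fisher's exact test, adjusted p = 3.49e-26) and the first 20 Mb of 3D had 19 of 143 (adjusted p = 1.15e-07). The window from 680 to 700 Mb on 2B had 15 higher genes of 81 (adjusted p = 9.2e-07) and the first 20 Mb of 5D had 12 of 79 (adjusted p = 0.000221). A total of 130 genes had 0 counts in every purple library and at least 1 FPKM in every white library, 58 of them in the lowered part of 1B, and 117 genes showed the reverse.

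In the lowered part of chromosome 1B, 76.7% of 484 genes expressed in white grain had a purple mean under 25% of the white mean, against 4.20% on the rest of 1B. The boundary of this part was fitted to the same measure, so the contrast is not independent of it. A few genes taking most of the counts would shift all genes alike. That is argued against, since the median log2 difference was -3.16 in this part and 0.22 on the rest of 1B. With libraries scaled outside the 100 highest genes, 353 genes of this part were called lower, against 350. That scaling moved the median of all tested genes only from 0.02 to -0.098, so it could hardly change the count. Counting of 1B reads on the copies on 1A and 1D is argued against too, since those copies differed from partners of other 1B genes by -0.0076 log2 (bootstrap SE 0.072). A segment that is absent or strongly diverged in the purple grain plants is a candidate explanation for the 76.7%. Replacement of the short arm by a rye arm, known from wheat breeding, would be such a case; it was not tested on sequence, and any link with grain colour stays open.

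Purple replicate 3 lay nearer to the white libraries than purple replicates 1 and 2. A swap with a white library is argued against, as 0% of the 91 genes in the lowered part of 1B without counts in purple replicates 1 and 2 stood at 50% or more of the white mean in it, and so is lower depth, as purple replicates 1 and 2 thinned to its total correlated at 0.778 with the white libraries against 0.852 for replicate 3. A first test of mixed-in white grain RNA decided nothing, since the lowered 1B genes stood at a median of 7.496% of the white mean in replicate 3 and 6.73% in replicates 1 and 2. In a second test, added because of that result, those 91 genes stood at a median of 0% of the white mean in replicate 3, and at 0.451% when summed, which argues against a mixture of 5% or more. A difference in grain material within the group stays open.

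Of 55 tested LEA and dehydrin genes 16 were called higher in purple grain, and the list did not pass with an estimated correlation (adjusted p = 0.951). A few genes taking most of the counts would shift all genes alike. That is argued against, as the median log2 difference was 2.39 for this list and 0.02 for all tested genes. Scaling outside the 100 highest genes moved the median of all tested genes only to -0.098, so it could hardly change the calls. Under it 17 LEA and dehydrin genes were called higher, against 16. Grain collected at different states of maturation could raise these genes and lower photosynthesis genes, whose median log2 difference was -1.08. A larger share of embryo or aleurone could raise them too, as the embryo and aleurone list had a median log2 difference of 1.05 and held 3.98% and 4.44% of summed FPKM in purple replicates 1 and 2, against 1.05% in purple replicate 3 and 0.381% to 1.05% in white grain. Maturation, tissue share and grain type cannot be told apart here, because both grain types were sampled at 1 time and any of them could give these differences. In addition, no list passed with an estimated correlation.

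The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 1391 higher and 1127 lower genes, the highest other split gave 0 of each, and 1 of the 10 gave as many. For gene lists the real split passed 8 and 7 of the 10 passed as many, with 16 for white replicate 1 with purple replicates 1 and 2 against the rest.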
